A study of Mus musculus with 42 samples.

How the data were processed

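Bone marrow MSCs of C57BL/6 mice were bought at an early passage and used at passage 9 to 10, per the labels. For RNA they were plated at 15000 cells/cm2, left to attach for 24 h and treated for 48 h with the solvent (DMSO at 0.1%), TBT (50 nM), AGN194204 (100 nM) or rosiglitazone (100 nM). The RNA samples had integrity numbers of 8.0 to 8.6. Strand-specific libraries with added ERCC spike-in RNA were sequenced as 75-nt read pairs, per the labels. Up to 12 libraries shared a sequencing run, and the run of each library is not given in the sources used here, so no within-run comparison was made. For ChIP-seq, cells treated with DMSO or TBT were fixed in 1% paraformaldehyde for 10 min, and 5 µg of DNA was precipitated with 2.5 µg of antibody to H3K4me3 or H3K27me3. The series has 42 samples: 24 RNA libraries, 16 ChIP libraries and 2 inputs, 1 per treatment. Groups and replicate numbers were taken from the sample labels.

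The authors deposited a table of raw read counts per gene symbol for the 24 RNA libraries. It has 45317 gene entries, 92 ERCC entries and 5 entries for reads given to no gene, and the latter were left out of library sizes and tests. Reads outside annotated genes made up 20.9% to 24.3% of all counts and ambiguous reads 1.85% to 2.02%. The submitters' processing notes name STAR, SAMtools, FastQC and DESeq2 without versions, and the builds GRCm38 and mm10. The program that counted the reads, and whether it used strand, is not given in the sources used here, so genes that overlap or have near-identical copies are uncertain. Several symbols in the table have been turned into dates and were kept as they stand. A second deposited table gives log2 values, made by the authors as log2 of the count divided by a factor per library, plus 1. It was used only to recover those factors for 18 libraries, which lay within 0.01% of median-ratio factors over genes and spike-ins together, and 6 columns of it were not used.

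For each ChIP library the authors deposited a list of islands with the ChIP read count and the input read count of each island. The same files give a p-value and an FDR per island, computed by the authors' caller, and the fold of ChIP reads over input reads scaled to the library. SICER is named in the submitters' processing notes, and the settings by the file names were a window of 200 bp, a gap of 600 bp and an FDR of 0.001. Islands were called per library, not on pooled libraries. For each mark the authors also deposited a table of differential peaks with log2 concentrations, log2 fold (DMSO minus TBT), p-value and FDR, and the submitters' processing notes name DiffBind. These tables list only peaks with an FDR of at most 0.05, and their values are the authors' own. They were used to describe and rank peaks, for the directions of peaks set against RNA calls and against the count test, and for the concentrations of groups without an island.

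Gene counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, in 1 fit of all 24 libraries with a term for treatment. This left 12529 genes, and p-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. The common spread between libraries was 5.24% (biological coefficient of variation). CPM are TMM-scaled, log2 CPM use a prior count of 2, and fold changes are given with the standard error of the fit. A limit for 0 counts uses 3 counts. Gene counts per library did not differ past the threshold between TBT (p = 0.645), AGN194204 (p = 0.357) or rosiglitazone (p = 0.11) and DMSO in exact two-sided permutation tests over 924 arrangements. No 2 libraries of a group agreed within sampling noise.

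The genes named in the text followed a rule. Against DMSO these were the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 1, all 6 treated libraries beyond all 6 DMSO libraries and a symbol that is not a predicted name. The first 3 members by adjusted p of each list with a called member were also taken, of which the text gives a part. Pparg, Rxra, Fabp4, Adipoq, Plin2, Lpl, Cebpa, Cebpb, Ezh2 and Runx2 were always included. Between compounds the 5 largest differences in each direction were named. For each mark these were the 5 deposited peaks with the smallest FDR in each direction, and peaks or tested regions on list genes, here given as counts with examples. The 21 H3K4me3 regions that passed the test were all named, which goes beyond the rule and was decided after their values were seen. This rule, the main tests, the lists and the other settings tried were fixed before the data were examined. The permutation tests of mark change between genes that rose or fell and genes not called, and the tests of gene counts per library, were added later.

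The 23 lists covered adipogenic regulators, adipogenesis inhibitors, adipocyte markers, targets of PPAR, LXR and RAR, fatty acid and cholesterol synthesis, thermogenic, osteoblast, chondrocyte, smooth muscle, matrix, and stem and stromal cell genes. They also covered macrophage and blood cell markers, endothelial markers, cell cycle genes, H3K4 and H3K27 methylation genes, metal and oxidative stress, endoplasmic reticulum stress, inflammatory and interferon-induced genes, and nuclear receptors. Some lists share genes: 13 of the 44 PPAR targets and 14 of the 33 adipocyte markers are in another list, and 0 of the 26 interferon-induced genes. Lists were tested on log2 CPM with camera of limma 3.58.1, with a preset correlation of 0.01, and p-values were adjusted over 69 tests. camera compares a list with the other genes. The same test with a correlation estimated per list was run beside it, and fry, which tests whether genes of a list move one way without comparing them with other genes.

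Overlaps of calls were set beside the number for independent lists and beside a split of the DMSO libraries. They were also set beside 20 simulations in which no gene changed and the DMSO group was simulated too. For the marks, islands of the 8 libraries of a mark were merged into regions, and a region was tested where all 8 libraries had an island on it, since reads outside islands were not used here. Reads of a library's islands on a region were summed and tested with edgeR as above, and the tested regions held 5514673 to 9873722 reads per library for H3K4me3 and 2578840 to 5783690 for H3K27me3. Counts and lengths of islands were compared by exact two-sided permutation tests. Gene positions came from a RefSeq gene table of GRCm38.p6, the same build, without strand or exons. A promoter is therefore any point within 2 kb of either end of a gene, and exon or intron positions are not given. Of the tested genes 12109 (96.6%) were found in that table, 575 of them by an older symbol. Permutation tests across genes used 100000 resamples.

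Each test across genes or regions was tried on simulated counts drawn from the real means and library sizes with 200 changed features, 50 per fold. All 4-fold gene changes were recovered, and false calls made up 2.40% to 7.47% of calls over the 6 comparisons. Alternatives were DESeq2 1.42.0, RLE and ERCC scaling, no low-count filter, a filter of CPM of at least 1 in 6 libraries (looser than filterByExpr here), only the 12 libraries compared, the replicate number as a block, and each library left out. For regions they were DESeq2, scaling by summed reads, islands in at least 6 libraries, islands covering at least 50% of a region, stricter islands and each library left out. A mark counted as present at a promoter with an island in at least 3 of the 4 DMSO libraries. Promoters of 1 kb and 5 kb, and islands in all 4 DMSO libraries, were also tried. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. DNA sequence was not analysed here, and results for 2 genes that the rule names are not reported here.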

Results

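Mesenchymal stromal cells (MSCs) grown out of mouse bone marrow, which can become fat, bone or cartilage cells, were kept undifferentiated and exposed to 1 of 4 treatments for 48 h. The treatments were the solvent dimethyl sulfoxide (DMSO, 0.1%), rosiglitazone (100 nM), AGN194204 (100 nM) and tributyltin (TBT, 50 nM). Rosiglitazone is a drug that activates the nuclear receptor PPARγ, the main regulator of fat cell formation. AGN194204 is a synthetic agonist of the retinoid X receptors (RXR), which form heterodimers with PPARγ and other nuclear receptors. TBT is an organotin pollutant known to activate both RXR and PPARγ. RNA was sequenced in 6 libraries per treatment. H3K4me3, a histone mark of active promoters, and H3K27me3, a mark of Polycomb-repressed chromatin, were mapped by ChIP-seq in 4 DMSO and 4 TBT libraries each. The title of the series frames the question as whether activating RXR changes chromatin and directs MSCs towards fat.

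Each RNA library held 3801758 to 5347365 counts on genes, with group means of 4539103 ± 307912 for DMSO, 4267021 ± 225490 for rosiglitazone, 4355278 ± 357363 for AGN194204 and 4412206 ± 561750 for TBT (SD, n = 6). Between 20.9% and 24.3% of counts fell outside annotated genes, and the 10 most abundant genes took 1.81% to 1.99% of gene counts. Mitochondrial transcripts made up 0.267% to 0.377%. Along the first principal component of log2 CPM (gene counts scaled to a common library size), which held 37.7% of the variance, the TBT and AGN194204 libraries lay between 8.41 and 15.5. DMSO and rosiglitazone libraries lay between -14.2 and -7.82 on the same axis. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

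TBT against DMSO showed which genes the organotin changed. Car3, a carbonic anhydrase abundant in fat cells, rose by 4.70 ± 0.15 on the log2 scale (SE, n = 6 per group), from 2.14 ± 1.07 to 57.1 ± 3.83 CPM (SD). Abca1, the pump that moves cholesterol out of cells, rose by 4.55 ± 0.11, from 7.55 ± 2.34 to 178 ± 13.1 CPM. Fabp4, the fatty acid-binding protein of fat cells, rose by 4.00 ± 0.16, from 2.24 ± 0.93 to 36.3 ± 4.61 CPM. Plin4, a lipid droplet coat protein, rose by 2.81 ± 0.07, from 38.1 ± 4.99 to 267 ± 16.9 CPM. The other large rises were those of the phosphodiesterase Pde1b (4.12 ± 0.25), the carbonic anhydrase Car2 (3.13 ± 0.26), the lactase-like protein Lctl (2.84 ± 0.23) and the synaptic adhesion molecule Nrxn2 (2.81 ± 0.28).

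The steepest falls under TBT within the naming rule were in genes with DMSO means of 3.15 CPM (Afp) to 21.5 CPM (Angptl7). Mcpt8, a granule protease of basophils, fell by 2.45 ± 0.40. Scg2, a secretory granule protein, fell by 2.28 ± 0.25. Ass1, an enzyme of arginine synthesis, fell by 2.04 ± 0.23 and the protease-activated receptor gene F2rl1 by 1.87 ± 0.27. Also lower were the receptor modifier Ramp3 (fell by 1.86 ± 0.33) and the secreted protein gene Angptl7 (fell by 1.73 ± 0.16). Tigit, an immune checkpoint receptor, fell by 1.60 ± 0.24 and the fetal serum protein gene Afp by 1.59 ± 0.39. Among genes fixed in advance, Pparg rose by 0.46 ± 0.06, from 44.3 ± 2.02 to 60.5 ± 4.47 CPM. Lpl, which frees fatty acids from lipoproteins, rose by 1.21 ± 0.04, Cebpa, an adipogenic transcription factor, by 0.76 ± 0.11 and the lipid droplet protein gene Plin2 by 0.47 ± 0.06. Ezh2, the methyltransferase that writes H3K27me3, fell by 0.30 ± 0.04, from 151 ± 5.77 to 123 ± 6.54 CPM, a call that ended at -0.21 with ERCC scaling. Cebpb stood at 0.09 ± 0.05, the bone regulator Runx2 at 0.01 ± 0.05 and Rxra at -0.01 ± 0.04, none past the threshold (adjusted p = 0.19, 0.95 and 0.91, edgeR). Adiponectin (Adipoq) had 1 count over the DMSO libraries and 0 elsewhere, where 0 counts allow up to 0.110 to 0.117 CPM over a group, counting error only.

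edgeR's quasi-likelihood test called 1878 genes higher and 1745 lower under TBT among 12529 tested, with Benjamini-Hochberg adjusted p of 1.95e-25 for Car3, 9.88e-29 for Abca1 and 0.0018 for Afp. Changes of at least 2-fold made up 156 of the rises and 44 of the falls, and the median size over called genes was 0.27 on the log2 scale. Scaling by the ERCC spike-ins in place of TMM moved the split to 1802 higher and 293 lower. Spike-in counts per 100 gene counts ran from 0.376 to 0.502 within DMSO and from 0.326 to 0.453 within TBT. The group means, 0.435 ± 0.041 and 0.407 ± 0.043 (SD), lay closer together than that spread. The change of split therefore does not show a change of total RNA. In simulated data at this depth the test recovered 44% of 1.2-fold, 80% of 1.5-fold and 92% of 2-fold changes in this comparison.

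**Figure D1:**
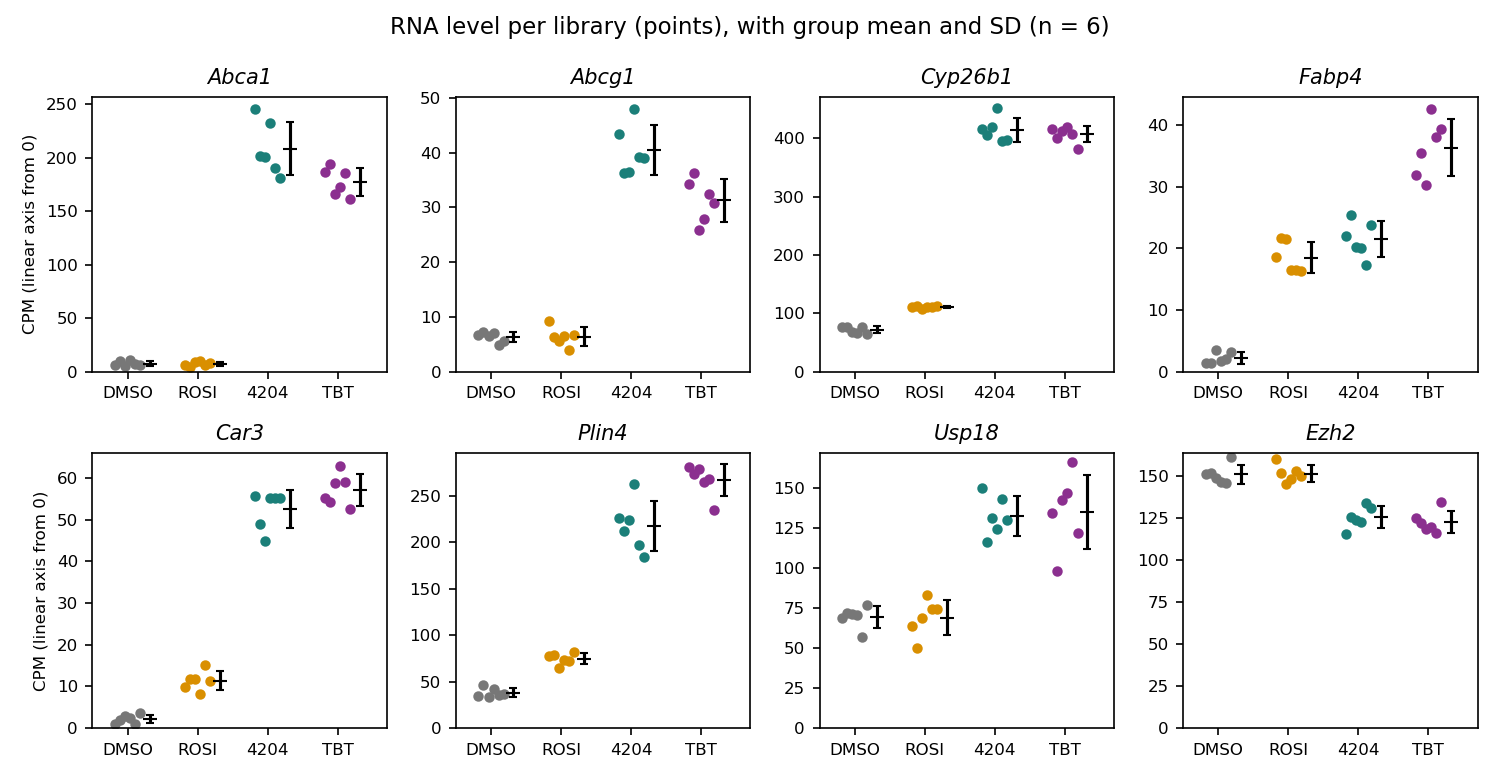
CPM of 8 genes on linear axes from 0, 1 point per library, with group means and SD bars (n = 6 for DMSO, ROSI, 4204 and TBT; ROSI is rosiglitazone and 4204 is AGN194204). Abca1 averaged 7.55 CPM in DMSO, 178 in TBT and 209 in AGN194204, while Fabp4 averaged 2.24 CPM in DMSO, 18.5 in rosiglitazone, 21.5 in AGN194204 and 36.3 in TBT.

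PPAR target genes moved one way under TBT: 21 of 28 measured rose and 0 fell (22 and 0 adjusted over the list alone), among them Pdk4, a brake on glucose oxidation (1.79 ± 0.05), and Lpl (1.21 ± 0.04). Of 15 adipocyte markers 13 rose and 0 fell (13 and 0 adjusted over the list alone), including Plin4 and Car3. Of 13 targets of the cholesterol-sensing liver X receptors (LXR) 9 rose and 2 fell (9 and 2 adjusted over the list alone), led by Abca1, its relative Abcg1 (2.30 ± 0.13) and the phospholipid enzyme gene Lpcat3 (0.75 ± 0.04). Fatty acid synthesis genes rose in 14 of 21 with 0 falls (16 and 0 adjusted over the list alone), for example Scd1 (0.46 ± 0.03) and Srebf1 (0.66 ± 0.06). Cholesterol synthesis genes rose in 11 of 24 with 0 falls (11 and 0 adjusted over the list alone), led by Insig1 (0.48 ± 0.05). Adipogenic regulators rose in 9 and fell in 2 of 20 (9 and 3 adjusted over the list alone), with Ebf2 at 1.62 ± 0.12 and Stat5a at 0.92 ± 0.07. The set test camera called all 6 lists higher, with adjusted p from 1.7e-17 for PPAR targets to 9.5e-04 for cholesterol synthesis. These 6 calls held with an estimated correlation (adjusted p from 2.5e-06 to 0.037).

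All 26 measured interferon-induced genes rose under TBT (26 adjusted over the list alone), among them the interferon regulator Usp18 (0.95 ± 0.09, from 69.3 to 135 CPM), the antiviral gene Ifi44 (1.13 ± 0.12) and Ddx58, a sensor of viral RNA (0.66 ± 0.07). The mean over this list lay above all 12 DMSO and rosiglitazone libraries in each of the 12 TBT and AGN194204 libraries. Beside this, 0 of 4 measured macrophage and blood cell markers passed the edgeR test (0 adjusted over the list alone, 0 by DESeq2, 2 at an unadjusted p under 0.05). The interferon list passed camera at adjusted p = 2.4e-16, but at adjusted p = 0.11 with an estimated correlation. Of 32 matrix genes 21 rose and 3 fell (21 and 6 adjusted over the list alone), led by the collagen VI chains Col6a2 (1.22 ± 0.06), Col6a1 (0.67 ± 0.04) and Col6a3 (0.84 ± 0.05). This list stood at adjusted p = 3.4e-08 by camera and adjusted p = 0.072 with an estimated correlation. Endoplasmic reticulum stress genes rose in 13 and fell in 3 of 24 (13 and 3 adjusted over the list alone), for example Trib3 (0.76 ± 0.07), at adjusted p = 5.9e-04 by camera and adjusted p = 0.21 with an estimated correlation.

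Cell cycle genes fell in 25 of 35 under TBT with 0 rises (30 and 0 adjusted over the list alone), among them the kinetochore proteins Cenpf (by 0.50 ± 0.06) and Cenpe (by 0.33 ± 0.04) and the replication helicase subunit Mcm3 (by 0.31 ± 0.03). The list passed camera at adjusted p = 1.8e-12 and with an estimated correlation (adjusted p = 0.023). With ERCC scaling 2 of these genes fell and 30 of 35 still had values below 0. The list of genes that write, read or erase H3K4 and H3K27 methylation went both ways, with 6 rises and 10 falls of 35 (7 and 10 adjusted over the list alone) and camera adjusted p = 0.57. Kdm6b, which removes H3K27 methylation, rose by 0.44 ± 0.06, and the Polycomb genes Ezh2 and Phf19 fell by 0.30 ± 0.04 and 0.42 ± 0.09. Under ERCC scaling this list had 5 rises and 1 fall, and its median went from -0.02 to 0.07.

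Targets of the retinoic acid receptors (RAR) rose in 4 and fell in 2 of 13 under TBT (4 and 2 adjusted over the list alone). Cyp26b1, which breaks down retinoic acid, rose by 2.50 ± 0.04, from 71.7 to 407 CPM, and the retinol dehydrogenase gene Dhrs9 by 0.91 ± 0.09. For this list camera gave adjusted p = 0.037, and adjusted p = 0.13 with an estimated correlation. The other lists did not pass camera. By fry, osteoblast (adjusted p = 0.0043), smooth muscle (0.0096), thermogenic (2.7e-06) and metal and oxidative stress genes (8.7e-04) moved higher. Stem and stromal cell genes (adjusted p = 6.9e-04, fry) and inflammatory genes (7.2e-04) moved lower. The osteoblast list mean lay above all 12 DMSO and rosiglitazone libraries in each of the 12 TBT and AGN194204 libraries. Osteoblast genes rose in 6 and fell in 3 of 18 (7 and 3 adjusted over the list alone), including a rise of Ogn (0.70 ± 0.07). Smooth muscle and myofibroblast genes rose in 7 and fell in 1 of 18 (8 and 2 adjusted over the list alone), with Lmod1 at 1.12 ± 0.10, at adjusted p = 0.073 by camera. Stem and stromal cell genes rose in 5 and fell in 5 of 20 (5 and 6 adjusted over the list alone), and the hyaluronan receptor gene Cd44 fell by 0.41 ± 0.03. Inhibitors of adipogenesis rose in 4 and fell in 5 of 16 (4 and 5 adjusted over the list alone). Nuclear receptors rose in 3 and fell in 2 of 20 (3 and 2 adjusted over the list alone), with a rise of the LXR gene Nr1h3 (1.31 ± 0.17). Genes of the metal and oxidative stress response rose in 4 and fell in 2 of 23 (5 and 2 adjusted over the list alone), led by Hmox1 (0.60 ± 0.04). Inflammatory genes rose in 2 and fell in 4 of 17 (2 and 5 adjusted over the list alone), with Il33 falling by 1.05 ± 0.10. Thermogenic genes rose in 3 and fell in 1 of 7 (3 and 1 adjusted over the list alone), with Fgf21 up by 2.08 ± 0.22 and the deiodinase gene Dio2 down (-2.16 ± 0.46). Chondrocyte genes rose in 1 and fell in 1 of 6 (2 and 1 adjusted over the list alone). Of 4 endothelial markers 1, Flt1, fell by 0.73 ± 0.22 (0 and 1 adjusted over the list alone), a call that ended with ERCC scaling. That scaling moved the median of all genes up by 0.0896 and left fewer falls in these lists: 1 of adipogenesis inhibitors with 4 rises, and 1 each of osteoblast genes, matrix genes, adipogenic regulators and nuclear receptors. It left 0 falls of LXR targets, RAR targets, endoplasmic reticulum stress genes and metal and oxidative stress genes.

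AGN194204 against DMSO asked the same of a ligand of RXR. Abca1 rose by 4.77 ± 0.11 on the log2 scale (SE, n = 6 per group), from 7.55 ± 2.34 to 209 ± 25.0 CPM, and Abcg1 by 2.66 ± 0.13, from 6.33 ± 0.91 to 40.4 ± 4.57 CPM. Car3 rose by 4.58 ± 0.15, Fabp4 by 3.25 ± 0.18 and Cyp26b1 by 2.53 ± 0.04, from 71.7 ± 5.71 to 414 ± 21.0 CPM. Further large rises were those of Car2 (3.36 ± 0.25), Pde1b (3.23 ± 0.27) and the serine protease inhibitor gene Serpinb9c (2.60 ± 0.36). Pparg rose by 0.63 ± 0.06, Lpl by 1.01 ± 0.04, Cebpa by 0.45 ± 0.11 and Plin2 by 0.35 ± 0.06.

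Among genes that met the naming rule, AGN194204 lowered Ass1 (by 1.74 ± 0.22) and Scg2 (by 1.62 ± 0.23) most steeply. Angptl7 fell by 1.58 ± 0.15, the calcineurin regulator Rcan2 by 1.58 ± 0.25 and the activin antagonist follistatin, Fst, by 1.56 ± 0.36. Tigit fell by 1.52 ± 0.23, F2rl1 by 1.5 ± 0.26 and the S100 protein gene S100a7a by 1.38 ± 0.27. Ezh2 fell by 0.27 ± 0.04. Cebpb (0.03 ± 0.05), Runx2 (-0.03 ± 0.05) and Rxra (-0.03 ± 0.04) did not pass the test. edgeR called 1600 genes higher and 1414 lower, 142 and 33 of them by at least 2-fold, with adjusted p of 1.11e-34 for Cyp26b1 and 0.0021 for Cebpa. ERCC scaling gave 908 higher and 300 lower, and the test recovered 48%, 84% and 94% of 1.2-fold, 1.5-fold and 2-fold changes in simulated data for this comparison.

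PPAR targets rose in 18 of 28 under AGN194204 with 0 falls (19 and 0 adjusted over the list alone), adipocyte markers in 10 of 15 with 0 falls (13 and 0 adjusted over the list alone). LXR targets rose in 9 of 13 with 1 fall (10 and 1 adjusted over the list alone). RAR targets rose in 6 and fell in 1 of 13 (7 and 3 adjusted over the list alone), with Dhrs3, which turns retinal into retinol, up by 1.56 ± 0.12 and the receptor gene Rarb by 0.62 ± 0.07. Fatty acid synthesis genes rose in 11 of 21 with 0 falls (14 and 0 adjusted over the list alone) and cholesterol synthesis genes in 8 of 24 with 0 falls (10 and 0 adjusted over the list alone). Adipogenic regulators rose in 10 of 20 with 2 falls (10 and 2 adjusted over the list alone). camera called these 7 lists higher, with adjusted p from 2.8e-16 for PPAR targets to 6.1e-04, and all 7 calls held with an estimated correlation (adjusted p from 3.4e-06 to 0.033). All 26 interferon-induced genes rose (26 adjusted over the list alone), at adjusted p = 1.7e-20 by camera and adjusted p = 0.061 with an estimated correlation. Cell cycle genes fell in 23 of 35 with 0 rises (26 and 0 adjusted over the list alone), at adjusted p = 4.0e-12 by camera and adjusted p = 0.024 with an estimated correlation. Under ERCC scaling 2 fell and 33 had values below 0.

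Matrix genes rose in 19 and fell in 6 of 32 under AGN194204 (21 and 6 adjusted over the list alone), with Col6a2 up by 0.86 ± 0.06, at adjusted p = 5.6e-05 by camera and adjusted p = 0.19 with an estimated correlation. Endoplasmic reticulum stress genes rose in 8 and fell in 1 of 24 (9 and 1 adjusted over the list alone), at adjusted p = 0.0086 and adjusted p = 0.34 with an estimated correlation. The remaining lists did not pass camera. By fry, osteoblast (adjusted p = 4.0e-04), thermogenic (7.5e-06), smooth muscle (0.034), metal and oxidative stress (0.022) and nuclear receptor genes (4.0e-04) moved higher. Stem and stromal cell genes (adjusted p = 0.0068, fry) and endothelial markers (2.6e-04) moved lower. Osteoblast genes rose in 6 and fell in 1 of 18 (7 and 2 adjusted over the list alone), smooth muscle genes rose in 5 and fell in 2 of 18 (10 and 3 adjusted over the list alone). The stem and stromal cell genes rose in 7 and fell in 7 of 20 (7 and 7 adjusted over the list alone). Methylation genes rose in 4 and fell in 9 of 35 (6 and 10 adjusted over the list alone) and adipogenesis inhibitors rose in 5 and fell in 3 of 16 (6 and 4 adjusted over the list alone). The nuclear receptors rose in 5 and fell in 2 of 20 (6 and 2 adjusted over the list alone). Inflammatory genes rose in 3 and fell in 3 of 17 (3 and 3 adjusted over the list alone) and metal and oxidative stress genes rose in 3 and fell in 2 of 23 (3 and 1 adjusted over the list alone). The thermogenic genes rose in 2 and fell in 1 of 7 (2 and 1 adjusted over the list alone). Chondrocyte genes rose in 1 and fell in 1 of 6 (2 and 1 adjusted over the list alone). The endothelial markers Flt1 and Pecam1 fell by 0.85 ± 0.22 and 1.02 ± 0.27 among 4 (1 and 2 adjusted over the list alone; without the low-count filter Pecam1 did not pass). Among macrophage and blood cell markers 0 of 4 macrophage and blood cell markers passed the edgeR test (0 adjusted over the list alone, 0 by DESeq2, 1 at an unadjusted p under 0.05). ERCC scaling left 3 rises of cholesterol synthesis genes, 8 of fatty acid synthesis genes, 14 of PPAR targets, 14 rises and 2 falls of matrix genes, 3 and 1 of adipogenesis inhibitors, 4 and 5 of stem and stromal cell genes and 2 and 2 of methylation genes. It left 0 falls of LXR targets, RAR targets, endoplasmic reticulum stress, metal and oxidative stress and chondrocyte genes. The median of all genes moved by only 0.0115 on that scale, so a lost call need not mean a smaller change.

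**Figure D2:**
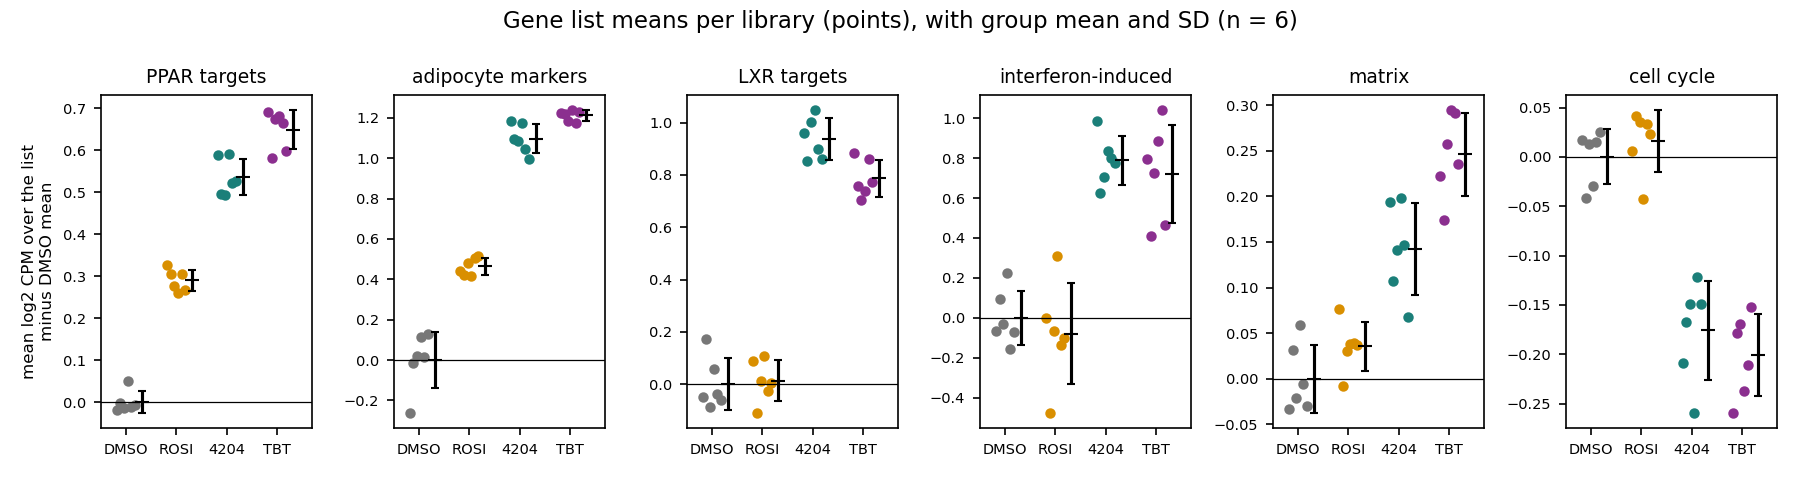
Mean log2 CPM over the measured genes of 6 lists minus the DMSO mean, 1 point per library, with group means and SD bars (n = 6; ROSI is rosiglitazone and 4204 is AGN194204). Adipocyte markers averaged 0.46 above DMSO in rosiglitazone, 1.10 in AGN194204 and 1.21 in TBT, and all 12 TBT and AGN194204 libraries lay above all DMSO and rosiglitazone libraries for interferon-induced genes and below them for cell cycle genes.

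Rosiglitazone against DMSO asked which genes a PPARγ agonist alone changed. Fabp4 rose by 3.03 ± 0.18 on the log2 scale (SE, n = 6 per group), from 2.24 ± 0.93 to 18.5 ± 2.48 CPM. Car3 rose by 2.37 ± 0.20, from 2.14 ± 1.07 to 11.3 ± 2.28 CPM, Pde1b by 2.12 ± 0.32 and Plin4 by 0.97 ± 0.09. The protease gene Tmprss11f rose by 1.45 ± 0.19, Prl2c3 by 1.25 ± 0.16, Hrct1 by 1.10 ± 0.17 and the acyl-CoA synthetase gene Acsbg1 by 1.04 ± 0.24. Prl2c3 belongs to a prolactin family with closely similar copies, so its count is uncertain. Pparg itself fell by 0.27 ± 0.07, from 44.3 ± 2.02 to 36.6 ± 3.49 CPM, a call that ended with DESeq2, without the low-count filter and with ERCC scaling. Lpl rose by 0.47 ± 0.04 and Plin2 by 0.40 ± 0.06.

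Large falls under rosiglitazone were those of the zinc finger gene Zfp607 (by 1.38 ± 0.30), Itih2, whose protein stabilises hyaluronan (by 1.11 ± 0.16) and Sned1 (by 0.75 ± 0.15). Faim2 fell by 0.58 ± 0.12, the transglutaminase gene Tgm2 by 0.54 ± 0.10, Rarb by 0.50 ± 0.08 and Smyd4 by 0.44 ± 0.08. Cebpa (0.37 ± 0.11, adjusted p = 0.11), Cebpb (0.13 ± 0.05), Runx2 (-0.07 ± 0.05), Ezh2 (0.00 ± 0.04) and Rxra (0.00 ± 0.04) did not pass the edgeR test. edgeR called 77 genes higher and 53 lower, 10 and 4 of them by at least 2-fold, with adjusted p from 5.36e-15 for Fabp4 to 0.036 for Pparg among the genes named here. The count was 33 with ERCC scaling, which ended the calls of Plin2, Acsbg1 and Sned1 among others, and went up to 236 (114 higher and 122 lower) when only the 12 libraries compared were fitted and 199 (97 and 102) without the low-count filter. Without DMSO replicate 3 it was 72 higher and 73 lower, so neither direction clearly outnumbered the other. ERCC scaling moved the median of all genes by -0.040 here, so a call that it ended need not mean a smaller change. In simulated data for this comparison 48%, 82% and 94% of 1.2-fold, 1.5-fold and 2-fold changes were recovered.

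PPAR targets rose in 7 of 28 under rosiglitazone with 0 falls (11 and 0 adjusted over the list alone), among them Angptl4, an inhibitor of lipoprotein lipase (0.64 ± 0.04), and Pdk4 (0.73 ± 0.06). Adipocyte markers rose in 5 of 15 with 0 falls (5 and 0 adjusted over the list alone). camera called both lists higher (adjusted p = 2.7e-20 and 5.0e-07), and both calls held with an estimated correlation (adjusted p = 1.4e-06 and 0.0041). Matrix genes rose in 4 of 32 with 0 falls (8 and 4 adjusted over the list alone), for example the basement membrane collagen gene Col4a1 (0.14 ± 0.03) and Col6a2 (0.26 ± 0.06). camera gave adjusted p = 0.022 and adjusted p = 0.43 with an estimated correlation. The list median was 0.04, and -0.002 under ERCC scaling. Nuclear receptors rose in 1 and fell in 2 of 20 (1 and 3 adjusted over the list alone), at adjusted p = 0.018 towards lower and adjusted p = 0.17 with an estimated correlation. Endothelial markers passed camera towards lower at adjusted p = 0.021, and had adjusted p = 0.051 with an estimated correlation, with 0 of 4 past the edgeR and DESeq2 tests (0 and 1 adjusted over the list alone; 1 at an unadjusted p under 0.05).

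The remaining lists did not pass camera under rosiglitazone. By fry, only macrophage and blood cell markers among them moved, towards lower (adjusted p = 0.020). RAR targets rose in 1 and fell in 2 of 13 (3 and 5 adjusted over the list alone), with Cyp26b1 up by 0.63 ± 0.05 while Rarb and Tgm2 fell. Adipogenic regulators rose in 1 and fell in 3 of 20 (2 and 4 adjusted over the list alone), with Ebf2 up by 0.53 ± 0.13 and Klf4 down (-0.41 ± 0.06). LXR targets rose in 1 of 13, Lpcat3 (0.20 ± 0.04), with 0 falls (1 and 0 adjusted over the list alone). Thermogenic genes rose in 1 of 7, Ebf2, with 0 falls (1 and 0 adjusted over the list alone). The metal and oxidative stress list rose in 1 of 23, Hmox1 (0.23 ± 0.04), with 0 falls (1 and 1 adjusted over the list alone). Osteoblast genes fell in 1 of 18, Enpp1 (-0.25 ± 0.05), with 0 rises (0 and 1 adjusted over the list alone). The stem and stromal cell genes fell in 1 of 20, Cxcl12 (-0.19 ± 0.04), with 0 rises (0 and 3 adjusted over the list alone). The cell cycle genes rose in 1 of 35, Rrm2 (0.20 ± 0.04), with 0 falls (1 and 1 adjusted over the list alone). edgeR called 0 members, as did DESeq2, in the lists of fatty acid synthesis (1 of 21 at an unadjusted p under 0.05), cholesterol synthesis (2 of 24), adipogenesis inhibitors (4 of 16), chondrocyte genes (0 of 6), and smooth muscle genes (3 of 18). The same held for macrophage and blood cell markers (0 of 4), methylation genes (3 of 35), endoplasmic reticulum stress (1 of 24), inflammatory genes (2 of 17) and interferon-induced genes (1 of 26). Adjusted over the list alone, 1 cholesterol synthesis gene and 1 inflammatory gene rose and 1 smooth muscle gene fell. Of all 69 list tests, 7 had a median, mean and test that differed in sign, and camera called 0 of those 7 at an adjusted p under 0.05. These were stem and stromal cell genes under TBT and AGN194204, inflammatory genes under AGN194204, and adipogenic regulators, LXR targets, osteoblast genes and methylation genes under rosiglitazone. With ERCC scaling 6 PPAR targets, 4 adipocyte markers and 1 matrix gene rose under rosiglitazone, 1 adipogenic regulator and 1 nuclear receptor fell with 0 rises, and 0 genes passed in the LXR, thermogenic, metal and oxidative stress, osteoblast, stem and stromal cell and cell cycle lists.

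TBT and AGN194204 were then set against each other in the same fit, at doses that differ (50 and 100 nM), to ask where an organotin and a pure RXR ligand diverge. Postn, which encodes the matrix protein periostin, was higher under TBT by 1.00 ± 0.20 on the log2 scale (SE, n = 6 per group), at 10.2 ± 2.39 against 5.09 ± 0.92 CPM. Fabp4 was higher under TBT by 0.75 ± 0.11, at 36.3 ± 4.61 against 21.5 ± 2.92 CPM, followed by Pde1b (0.89 ± 0.17), the cationic amino acid transporter gene Slc7a3 (0.71 ± 0.10) and Trim46 (0.66 ± 0.15). Slco4a1 (-0.96 ± 0.18), Afap1l2 (-0.92 ± 0.16), Fgl2 (-0.91 ± 0.18), the phosphatase gene Ptpn22 (-0.81 ± 0.16) and Tnfaip2, a gene induced by tumour necrosis factor (-0.79 ± 0.10), were lower under TBT.

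edgeR called 51 genes higher and 55 lower under TBT than under AGN194204, 1 and 2 of them by at least 2-fold, with adjusted p of 6.86e-06 for Tnfaip2 and 0.0050 for Postn. With only the 12 libraries compared 31 were higher and 30 lower, and ERCC scaling left 20 calls (13 higher and 7 lower) and ended those of Ptpn22 and Trim46. Of 10451 genes with a mean log2 CPM of at least 3, 10187 (97.5%) had a 95% interval of the difference that lay within 1.5-fold, with a median interval half-width of 0.13. The test recovered 42%, 82% and 92% of 1.2-fold, 1.5-fold and 2-fold changes in simulated data for this comparison.

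TBT and rosiglitazone were also compared, again at different doses. Abca1 was higher under TBT by 4.62 ± 0.12 (178 ± 13.1 against 7.24 ± 2.18 CPM), Car3 by 2.34 ± 0.11, Abcg1 by 2.29 ± 0.13, the matrix protein gene Thsd4 by 2.16 ± 0.34 and the cytoskeletal adaptor gene Sntb1 by 2.09 ± 0.21. Scg2 (-2.43 ± 0.25), Ass1 (-1.90 ± 0.23), Ramp3 (-1.73 ± 0.33), the osteoclast cytokine gene Tnfsf11 (-1.46 ± 0.25) and Angptl7 (-1.37 ± 0.16) were lower under TBT. edgeR called 1908 genes higher and 1690 lower, 129 and 33 by at least 2-fold, with adjusted p of 1.38e-28 for Abca1 and 1.03e-04 for Ramp3. ERCC scaling moved the median of all genes by 0.13 on the log2 scale and the share of calls that were higher from 53.0% to 93.4%. In simulated data for this comparison 46%, 84% and 92% of 1.2-fold, 1.5-fold and 2-fold changes were recovered.

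AGN194204 and rosiglitazone, both at 100 nM, showed the same leading gene, Abca1, higher under AGN194204 by 4.85 ± 0.11 (209 ± 25.0 against 7.24 ± 2.18 CPM). Abcg1 was higher by 2.65 ± 0.13, the growth factor gene Pdgfb by 2.56 ± 0.35, Phyhip by 2.24 ± 0.37 and the protease gene Pappa2 by 2.22 ± 0.27. Scg2 (-1.77 ± 0.23), Ass1 (-1.60 ± 0.23), Rcan2 (-1.36 ± 0.26), Ngef (-1.26 ± 0.12) and Angptl7 (-1.22 ± 0.16) were lower under AGN194204. edgeR called 1697 genes higher and 1400 lower, 135 and 17 by at least 2-fold, with adjusted p of 1.24e-29 for Abca1 and 9.99e-05 for Rcan2. ERCC scaling gave 1162 higher and 184 lower, and 48%, 86% and 92% of 1.2-fold, 1.5-fold and 2-fold changes were recovered in simulated data for this comparison.

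The calls against DMSO overlapped most between TBT and AGN194204. Both compounds raised 1300 genes and lowered 1082, with 1 called in opposite directions, 2382 genes in all. Independent lists of these lengths would share 437. Simulated groups without any changed gene, set against 1 simulated DMSO group, shared 0. Few calls can arise where no gene changed, so this 0 does not measure what the shared DMSO group adds. With the 6 DMSO libraries split 3 and 3 between the comparisons, a median of 1401.5 genes were shared over 20 values (1350 to 1450), where independent lists would share 220. Of the 2382 genes, 45 were also called between TBT and AGN194204. The covariance of the fold changes was 0.0612 against 0.0039 in the simulation, and the correlation across genes, which are not independent replicates, was 0.907 against 0.492. With split DMSO libraries the median correlation was 0.809.

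Rosiglitazone shared fewer calls, from a list of 130. As above, the simulation held no changed gene, so its 0 shared calls set no baseline for these pairs. TBT and rosiglitazone both raised 65 genes and lowered 24, with 9 in opposite directions, where independent lists would share 18.9, the simulation shared 0, and split DMSO libraries gave a median of 43.5 (33 to 58; independent lists 6.22). AGN194204 and rosiglitazone both raised 66 and lowered 14, with 14 in opposite directions, where independent lists would share 15.8, the simulation shared 0, and split DMSO libraries gave 39 (31 to 50; independent lists 5.30). The covariances were 0.0140 and 0.0118 against 0.0039 in both simulations. The correlations were 0.412 and 0.372. The simulated 0.493 and 0.491 arise from the shared DMSO group without any changed gene, so they are no baseline for these values. With split DMSO libraries, where the comparisons share no DMSO library, the median correlations were 0.285 and 0.241, both positive. Pparg was among the genes that went opposite ways, higher under TBT and AGN194204 and lower under rosiglitazone. Its call under rosiglitazone ended with DESeq2, without the low-count filter and with ERCC scaling, so this opposite direction is not settled.

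**Figure D3:**
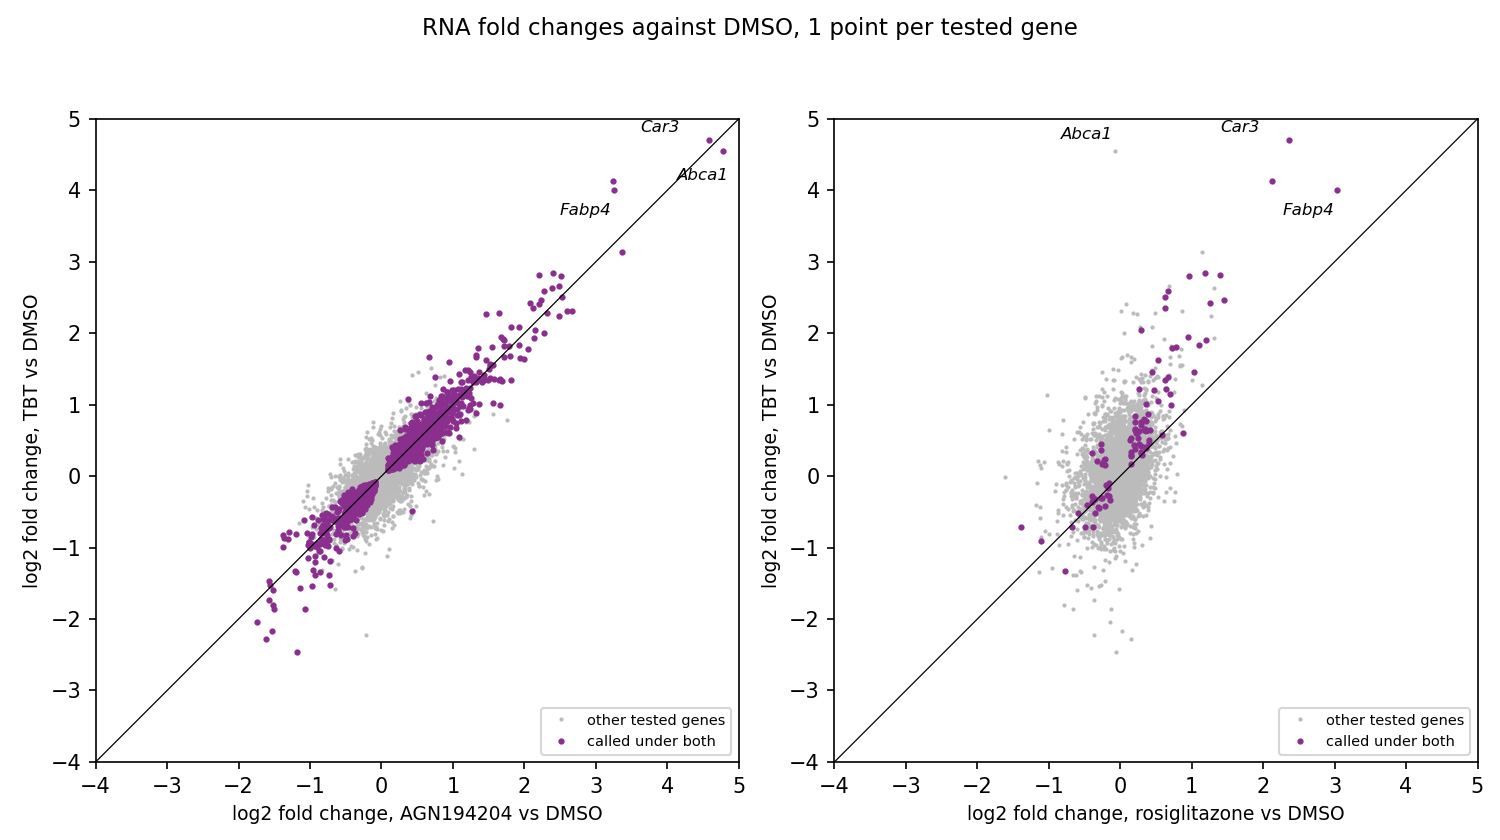
Log2 fold change against DMSO under TBT (vertical axis) and under AGN194204 (left) or rosiglitazone (right, horizontal axes), 1 point per tested gene, with genes called under both compounds in purple and a line of equal change. Abca1 rose by 4.55 under TBT and by 4.77 under AGN194204, and Fabp4 by 4.00 under TBT and by 3.03 under rosiglitazone.

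H3K4me3 islands, the stretches of enrichment over input that the authors' deposited files list per library, were as many and as wide under TBT as the spread between libraries allows to tell. TBT libraries had 19943.5 ± 1446 islands against 20831.2 ± 2662 in DMSO (SD, n = 4 per group; exact two-sided permutation test, p = 0.60), which covered 77.6 ± 7.97 and 80.9 ± 4.76 Mb (p = 0.457, exact). H3K27me3 islands numbered 26606.5 ± 5319 under TBT and 21851.8 ± 4940 in DMSO (p = 0.257, exact) and covered 169 ± 10.2 and 141 ± 25.4 Mb (p = 0.0571, exact). Reads in islands came to 7.54 ± 1.96 and 8.33 ± 1.54 M for H3K4me3 (p = 0.457, exact) and 10.2 ± 1.14 and 8.49 ± 1.58 M for H3K27me3 (p = 0.143, exact). Adjusted over the 6 tests the p-values ran from 0.343 to 0.60, and the smallest p that 70 arrangements allow is 0.0286. Without DMSO replicate 4 the H3K27me3 cover was 37.1 Mb wider under TBT (p = 0.0286, exact). Single libraries moved these differences. H3K4me3 islands under TBT minus DMSO went from -888 to 413.5 without DMSO replicate 3 and to -1588 without TBT replicate 4. With islands of at least 2-fold over input the difference was 484.5, so its direction was not settled. H3K4me3 reads under TBT minus DMSO went from -0.79 to -0.023 M without DMSO replicate 1 and to -1.71 M without TBT replicate 1, and H3K4me3 cover from -3.29 to -0.94 Mb without TBT replicate 4 and to -6.58 Mb without TBT replicate 1. The H3K27me3 difference went from 4755 to 2286 islands without TBT replicate 4. Without DMSO replicate 2, H3K27me3 cover went from 28.4 to 16.9 Mb and H3K27me3 reads from 1.71 to 0.937 M.

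Of the H3K4me3 regions that edgeR called under TBT, all with an island in all 8 libraries, the one with the largest change was at Abca1. Its region (chromosome 4, 53151201 to 53162600, GRCm38, over a gene end) rose by 1.37 ± 0.10 on the log2 scale (SE, n = 4 per group), from 36.0 ± 5.44 to 93.7 ± 8.03 CPM over the reads in tested regions (SD). The region at an end of Angptl4 (chromosome 17, 33774601 to 33788800) rose by 0.60 ± 0.05, from 121 ± 4.07 to 184 ± 7.98, and that at Wisp2, a secreted regulator of Wnt signalling (chromosome 2, 163819201 to 163829000), by 0.78 ± 0.08, from 37.4 ± 1.53 to 64.5 ± 3.60. Gbp6, an interferon-induced GTPase gene with closely similar neighbours (chromosome 5, 105283001 to 105297200), rose by 0.95 ± 0.11, and Col6a1 (chromosome 10, 76715401 to 76737200) by 0.62 ± 0.07.

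Further H3K4me3 rises lay at gene ends of the carnitine transporter gene Slc22a5 (0.42 ± 0.06; chromosome 11, 53887001 to 53893000), Cyp26b1 (0.27 ± 0.04; chromosome 6, 84578001 to 84592800) and Zbtb16 (0.47 ± 0.08; chromosome 9, 48830601 to 48838600). Interferon-induced genes gave 6 more: Mx2 (0.46 ± 0.07; chromosome 16, 97530801 to 97547600), Ifi44 (0.65 ± 0.11; chromosome 3, 151739801 to 151751800), Rsad2 (0.42 ± 0.07; chromosome 12, 26449601 to 26458400), Usp18 (0.37 ± 0.06; chromosome 6, 121241601 to 121254200), Ifit3 (0.50 ± 0.09; chromosome 19, 34580001 to 34591800) and Zbp1 (0.54 ± 0.09; chromosome 2, 173213801 to 173220800). H3K4me3 fell at Fbln2, which encodes the matrix protein fibulin-2 (by 0.53 ± 0.08; chromosome 6, 91185401 to 91225400), at Msln and Mslnl (by 0.63 ± 0.11; chromosome 17, 25742801 to 25761400) and at Gm29595 (by 0.80 ± 0.13; chromosome 19, 45298401 to 45314400). It also fell inside Trio (by 0.34 ± 0.05; chromosome 15, 27770601 to 27795200), Kcnh2 and Gm15589 (by 0.71 ± 0.11; chromosome 5, 24325001 to 24336200) and Gse1 (by 0.77 ± 0.13; chromosome 8, 120263801 to 120283000), and 12.3 kb from Fgd2 (by 0.69 ± 0.12; chromosome 17, 29391801 to 29402600).

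edgeR tested 12813 H3K4me3 regions with an island in all 8 libraries, 30.0% of 42705 merged regions, and called 14 higher and 7 lower, with adjusted p from 8.08e-05 for Abca1 to 0.047 for Zbp1. Leaving out 1 library at a time gave 5 calls (without DMSO replicate 2) to 11 (without DMSO replicate 3), and those of Abca1, Angptl4, Wisp2, Gbp6 and Col6a1 were made in all 8 such fits. DESeq2 called 136 regions (71 higher and 65 lower), while regions with an island in at least 6 libraries gave 5 calls. In simulated data the test recovered 28%, 82% and 96% of 1.2-fold, 1.5-fold and 2-fold changes of H3K4me3 regions.

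**Figure D4:**
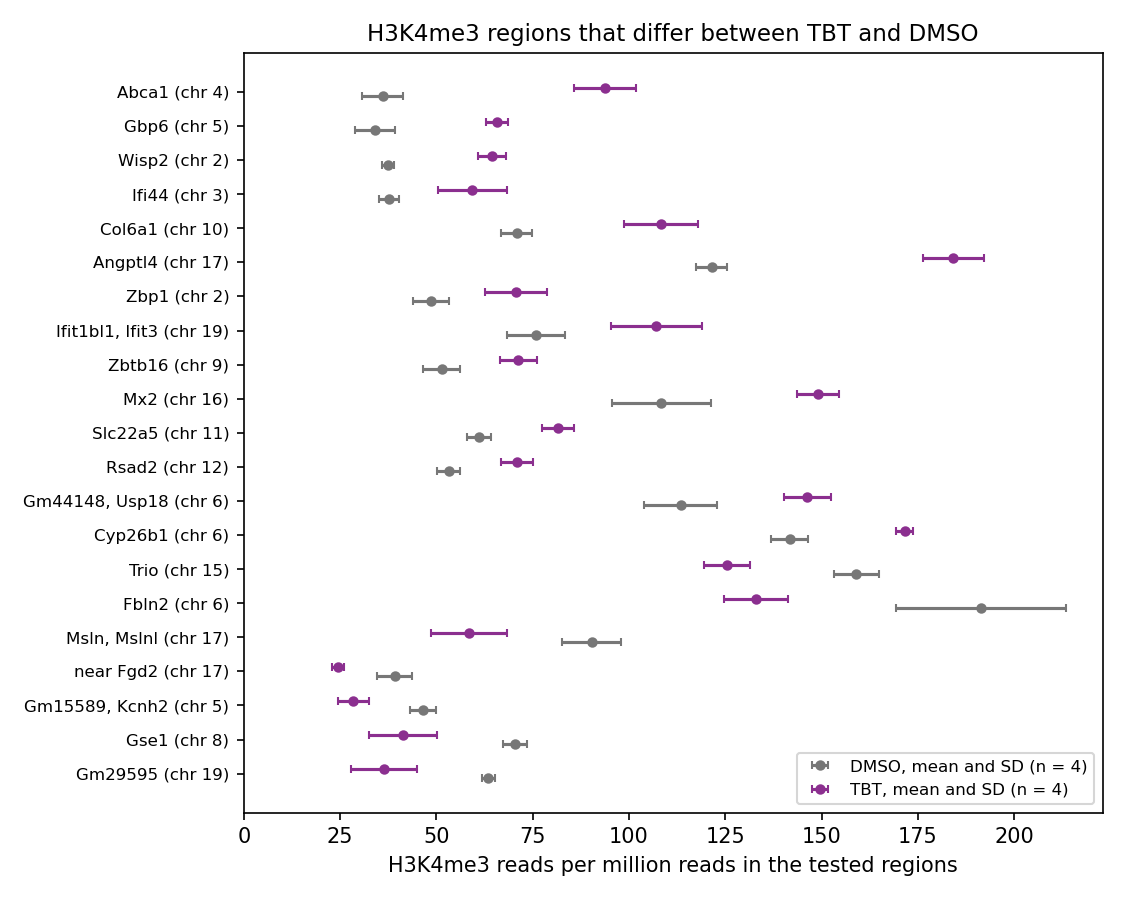
H3K4me3 CPM over the reads in the tested regions (linear axis from 0) for the 21 regions called by edgeR, with means as points and SD as bars for 4 DMSO and 4 TBT libraries. The Abca1 region averaged 36.0 in DMSO and 93.7 in TBT, and the Fbln2 region 191 in DMSO and 133 in TBT.

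No H3K27me3 region passed the test: edgeR called 0 of 2882 regions with an island in all 8 libraries, 4.12% of 70026 merged regions, with 176 at an unadjusted p under 0.05 and 0.0975 as the lowest adjusted p. DESeq2 called 26 of them (17 higher and 9 lower), with 243 at an unadjusted p under 0.05. The spread between libraries was 34.2% (biological coefficient of variation) against 9.75% for H3K4me3, and in simulated data 8% of 1.5-fold, 22% of 2-fold and 90% of 4-fold changes of H3K27me3 regions were recovered, so most changes of 2-fold or less would have been missed at this depth and spread. Only reads within each library's own islands were counted, so this spread includes differences in how far islands reached. Islands covering at least 50% of a region in all 8 libraries were found in 100 H3K27me3 regions (0 called) and 2475 H3K4me3 regions (12 called).

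The authors' deposited table lists 246 H3K4me3 peaks that differ, 24 higher under TBT and 222 higher in DMSO, with their own log2 fold (DMSO minus TBT) and FDR per peak. Of their concentrations, 86 for TBT and 2 for DMSO were at or below 0. Each treatment had 1 input, so in island calls a difference between inputs cannot be told apart from treatment. Input reads within H3K4me3 islands came to 1.48 to 1.67 M in TBT libraries and 1.23 to 1.38 M in DMSO libraries. The ratio of ChIP to input depth was 0.65 to 1.37 in TBT and 0.95 to 1.67 in DMSO libraries of this mark. Whether this bears on the directions of the peaks was not tested. Highest in rank under TBT in the authors' deposited table were Abca1 (fold -1.59, FDR 1.58e-14; the region given above), the interferon-induced GTPase gene Iigp1 (fold -1.13, FDR 1.09e-06; chromosome 18, 60373201 to 60390800), Wisp2 (fold -0.97, FDR 1.25e-06), Angptl4 (fold -0.81, FDR 5.49e-04) and Ifit3 with Ifit1bl1 (fold -0.78, FDR 9.66e-04). Higher in DMSO in the authors' deposited table were Gm30562 (fold 5.98; chromosome 11, 112809001 to 112816600) and the body of the glutamate transporter gene Slc1a2 (fold 5.90; chromosome 2, 102758201 to 102765800). The authors' deposited table also has as higher in DMSO Gm19385 with Gm34425 (fold 5.90; chromosome 9, 120861801 to 120872000), the body of Abtb2 (fold 4.79; chromosome 2, 103684601 to 103693400) and Msln with Mslnl (fold 1.15). At Gm30562, Slc1a2 and Gm19385 TBT stood at the lowest concentration that the authors' deposited table gives for it (-0.33), so these folds are not measured sizes. Of these 246 peaks in the authors' deposited table, 43 (17.5%) lay on regions with an island in all 8 libraries, all 43 with the same sign in the count test, and 158 had islands in libraries of 1 group only. At an FDR under 0.01 the authors' deposited table keeps 86 H3K4me3 peaks, 7 higher under TBT and 79 higher in DMSO. Genes of the fixed lists carried 19 of the H3K4me3 peaks in the authors' deposited table, 8 higher under TBT and 11 higher in DMSO.

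The authors' deposited table lists 4329 H3K27me3 peaks, 2055 higher under TBT and 2274 higher in DMSO, with a median absolute log2 fold of 4.25. Higher under TBT in the authors' deposited table were peaks over ends of Aatk and Baiap2 (fold -7.45; chromosome 11, 120005801 to 120027400) and inside Dlgap2 (fold -7.11; chromosome 8, 14814201 to 14834000). The authors' deposited table also has peaks higher under TBT at Gm39261 (fold -7.00; chromosome 8, 117763201 to 117787000), at the lipid transporter gene Abca7 with Arhgap45 (fold -5.93; chromosome 10, 80011001 to 80032600) and 15.9 kb from Ankrd16 (fold -6.82; chromosome 2, 11806201 to 11823200). Higher in DMSO in the authors' deposited table were peaks inside Gm34799 (fold 7.83; chromosome 17, 9887001 to 9908200) and inside Sox5, a cartilage transcription factor (fold 7.73; chromosome 6, 144529801 to 144575800). The authors' deposited table also has peaks higher in DMSO 11.6 kb from Hyal6 (fold 7.33; chromosome 6, 24701601 to 24721600), at Gm14390 (fold 6.63; chromosome 2, 176728801 to 176772000) and inside Nr3c2, the mineralocorticoid receptor gene (fold 7.3; chromosome 8, 77215801 to 77231200). FDR in the authors' deposited table ran from 1.34e-21 to 6.30e-14 over these 10 peaks. Except at Gm14390, Abca7 and Ankrd16, these folds set 1 group against the lowest concentration that the authors' deposited table gives for the other (-0.22 for TBT, -0.19 for DMSO), so they are not measured sizes. At Sox5 in TBT, Nr3c2 in TBT and Dlgap2 in DMSO that lowest value of the authors' deposited table stands although 2, 1 and 1 libraries had an island. The authors' deposited table has 877 DMSO and 1065 TBT values at or below 0, which enter the median of 4.25, and 316 of these had an island. Of the 4329 peaks, 49 (1.13%) lay on regions with an island in all 8 libraries, and 3271 in the authors' deposited table had islands in libraries of 1 group only. Genes of the fixed lists carried 52 H3K27me3 peaks of the authors' deposited table, 30 higher under TBT and 22 higher in DMSO. Among them were a peak at Ezh2 that was higher in DMSO in the authors' deposited table (fold 6.08; chromosome 6, 47529601 to 47542000) and peaks higher under TBT at Col6a1 (fold -6.53; chromosome 10, 76708601 to 76729400) and inside Rxra (fold -6.09; chromosome 2, 27714601 to 27733600), all 3 against the same lowest values.

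Genes whose promoter region gained H3K4me3 under TBT also gained RNA. All 14 of them rose, from Abca1 (4.55 ± 0.11), Wisp2 (2.59 ± 0.11) and Cyp26b1 (2.50 ± 0.04) to Rsad2 (0.61 ± 0.08), against 15.4% of 11159 expressed genes with a tested H3K4me3 region (Fisher's exact test, p = 4.22e-12, adjusted p = 4.22e-11 over 10 tests). The test treats genes as independent, but Mx2, Ifi44, Rsad2, Usp18, Ifit3 and Zbp1 belong to the interferon-induced list, whose estimated correlation was 0.66. Only the H3K4me3 calls of Abca1, Angptl4, Wisp2, Gbp6 and Col6a1 held whichever library was left out. The 2 expressed genes at regions with less H3K4me3, Fbln2 and Msln, stood at 0.12 ± 0.03, a rise, and -0.06 ± 0.05 (0 of 2 fell; Fisher's exact test, p = 1). Of 18 genes with an H3K4me3 peak higher under TBT in the authors' deposited table, 15 rose (Fisher's exact test, p = 3.35e-10, adjusted p = 1.68e-09). Of 25 genes with an H3K4me3 peak lower under TBT in the authors' deposited table, 6 fell (24% against 14.4%; Fisher's exact test, p = 0.161, adjusted p = 0.322) and 3 rose (p = 0.787, adjusted p = 0.984, Fisher's exact test). Usp18 was among these 3, although another region at this gene gained H3K4me3 in the count test. Its lower peak (chromosome 6, 121268601 to 121275200) had a fold of 1.21 and an FDR of 0.037 in the authors' deposited table. Over all tested H3K4me3 regions, the 1724 genes that rose had a median H3K4me3 change of 0.02 and the 1610 that fell of -0.02, against -0.003 for genes not called (permutation tests across genes, p = 1e-05, the smallest that 100000 resamples give, adjusted p = 2e-05). Genes with an H3K27me3 peak lower under TBT in the authors' deposited table fell in 33 of 184 (17.9% against 12.7% of all 3751; Fisher's exact test, p = 0.0309, adjusted p = 0.103). The other 3 pairings of H3K27me3 peaks with RNA gave adjusted p from 0.713 to 1. H3K27me3 change did not differ between the 210 genes that rose and those not called (0.03 and 0.03; permutation p = 0.991), nor for the 127 that fell (0.02; permutation p = 0.785).

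Genes with both marks at their ends in DMSO tended upwards under TBT. Each mark was scored on its own at either end of a gene. The marks therefore need not lie at the same end, and promoters that carry both were not singled out. The 783 expressed genes with H3K4me3 and H3K27me3 islands within 2 kb of a gene end, each in at least 3 of the 4 DMSO libraries, had a median log2 change of 0.05 against -0.01 over all 12109 genes (permutation test across genes, p = 1e-05, the smallest that 100000 resamples give, adjusted p = 4e-05), and 19.5% of them rose and 10.5% fell. The median was 0.02 over 1280 genes with 5 kb on each side (p = 2e-05, permutation) and 0.06 over 381 genes with islands in all 4 DMSO libraries (p = 1e-05, permutation). Genes with H3K4me3 alone numbered 10371, with a median of -0.01 (p = 0.0859, adjusted p = 0.115, permutation), and genes with neither mark 858, with a median of -0.04 (p = 6e-05, adjusted p = 1.2e-04, permutation). The 97 genes with H3K27me3 alone had a median of -0.003 (p = 0.874, permutation), which became 0.04 (p = 0.0245, permutation) with 5 kb on each side of a gene end, and 0.04 over 56 genes with islands in all 4 DMSO libraries (p = 0.118, permutation). Mean expression differed between these classes, with a median log2 CPM of 5.79 for H3K4me3 alone and 3.79 for both marks, and genes are not independent replicates.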

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

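The blood cell and depth tests of interferon-induced genes, the threshold and read-counting tests of H3K27me3 peaks and the test of chromosome copies were chosen after the results were seen. The others were planned.

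Interferon-induced genes rose under TBT and AGN194204 without an interferon among the treatments. The mean over the list lay above all DMSO and rosiglitazone libraries in 12 of 12 treated libraries, so a few odd libraries do not account for it. Depth is argued against by the 8 treated libraries with gene counts within the range of the others (4047841 to 5087215), since all 8 had list means above all of those. A response of the MSCs to RXR ligands may remain, as a hypothesis found and tested on the same data, and batch of culture was not tested. Blood or immune cells in the treated cultures stay open too, since 0 of 4 measured macrophage and blood cell markers rose in either comparison but only 4 of 24 were measured, most of them at low counts.

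The authors' deposited table lists 4329 H3K27me3 peaks while edgeR called 0 of 2882 regions with an island in all 8 libraries. Of those peaks 98.9% had islands in some libraries only, which islands near the calling threshold may give. Their islands had a median fold over input of 1.41, and so did islands in regions of all 8 libraries (1.97 and 6.88 for H3K4me3). This comparison cannot decide the point, because H3K27me3 islands in regions of all 8 libraries were themselves weakly enriched. An H3K27me3 island was also listed on mitochondrial DNA in every library but DMSO replicate 1 and TBT replicate 1, at 1.09 to 1.21 times input. Islands near the threshold therefore stay open as an explanation. Reads counted only within called islands are argued against, because 50.3% of groups without any island had a concentration above the floor in the authors' deposited table. The sign of the fold was the same in 93.9% of the 49 peaks that the count test also covers, which is what a real difference needs, but both rest on the same reads.

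H3K27me3 islands were uneven over chromosomes in both groups, from 1.26 per Mb on chromosome 16 and 2.26 on chromosome 1 to 13.7 on chromosome 6 and 16.8 on chromosome 19 in DMSO. Input reads per kb within H3K4me3 islands (the median of a chromosome over the median of the autosomal values) were 0.724 on chromosome 16 and 1.12 on chromosome 6 in DMSO, and 0.711 and 1.17 in TBT. Over 19 autosomes this input level followed island density (Pearson r = 0.936, Spearman rho = 0.942, p = 1e-05, the smallest that 100000 permutations give; adjusted p = 1.5e-05 over 6 relations; r = 0.894 without the 2 farthest chromosomes). Gene density as the whole cause is argued against by r = 0.930 once it was taken out. Unequal copies of chromosomes in the cultured cells may be a candidate explanation, though input outside those islands was not used here, and no effect of treatment was tested, as the pattern is in both groups.

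Some single libraries stood apart from the rest of their group, 14 of 316 groups of values (4.43%), where chance gives about 1 in 20 groups. TBT replicate 2 had 1.85% ambiguous reads against 1.95% to 2.02%. It also lay at 13.7 on the third principal component (other TBT libraries -0.56 to 4.32) and at 12.8 on the second (-7.72 to 3.83). Its differences from them came to 3.41 to 4.84 times sampling noise (chi-square per degree of freedom), against 1.46 to 2.40 among the others, and edgeR called 3884 genes under TBT without it. H3K4me3 DMSO replicate 1 had 10.6 M reads in islands against 7.43 to 7.72 M, and 122 reads per kb of island against 93.5 to 97.7. H3K4me3 DMSO replicate 3 had a median island length of 2800 bp against 3400, and H3K27me3 TBT replicate 1 a ratio of ChIP to input depth of 0.989 against 0.703 to 0.733. In CPM, Pde1b stood at 7.48 in rosiglitazone replicate 1 (others 3.46 to 4.95), Plin4 at 235 in TBT replicate 6 (266 to 281) and Ramp3 at 4.81 in AGN194204 replicate 6 (1.47 to 2.70). Tmprss11f stood at 10.2 in rosiglitazone replicate 4 (14.7 to 16.6) and Sntb1 at 4.51 in AGN194204 replicate 5 (6.53 to 7.57). Prl2c3 stood at 4.47 in DMSO replicate 5 (3.51 to 3.82) and S100a7a at 8.65 in DMSO replicate 1 (6.24 to 7.06). The mean of PPAR targets was 0.051 above the group mean in DMSO replicate 4 (others -0.02 to -0.002), and that of adipocyte markers -0.26 in DMSO replicate 1 (-0.02 to 0.13).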

How the results depend on the processing

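Every alternative used here was planned. ERCC scaling gave 2095 calls for TBT, 33 for rosiglitazone, 1208 for AGN194204, 20 for TBT against AGN194204 and 1346 for AGN194204 against rosiglitazone. The cause was not tested. Rosiglitazone had 199 calls without the low-count filter and 236 with only the 12 libraries compared, a setting that gave 61 for TBT against AGN194204. With 1 library left out, calls ran from 3183 to 3884 for TBT, 93 to 145 for rosiglitazone, 2621 to 2949 for AGN194204, 3174 to 3718 for TBT against rosiglitazone, 81 to 131 for TBT against AGN194204 and 2572 to 3111 for AGN194204 against rosiglitazone. Of 69 list tests camera called 27, and 17 with an estimated correlation. fry, which does not compare a list with other genes, called 40, and 26 of these were camera calls too. At a change of at least 1.5-fold the pairs of compounds shared 385, 27 (TBT and rosiglitazone) and 21 calls, and with split DMSO libraries, which have fewer samples, 1401.5, 43.5 and 39.

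H3K4me3 islands under TBT minus DMSO turned to 484.5 islands and 0.910 Mb at 2-fold or more over input, and ran from -1588 to 413.5 islands with 1 library left out, the highest without DMSO replicate 3. H3K27me3 cover was 16.9 to 37.1 Mb wider with 1 library left out. H3K4me3 regions with a call numbered 136 by DESeq2, 5 with islands in at least 6 libraries, 12 with islands covering 50% of a region, and 5 to 11 with 1 library left out: 6 without DMSO replicate 1, 5 without 2, 11 without 3 and 9 without 4, and 9, 10, 7 and 7 without TBT replicates 1 to 4. DESeq2 called 26 H3K27me3 regions. The authors' deposited table has 86 H3K4me3 peaks at an FDR under 0.01. Genes with H3K27me3 alone had a median of -0.0092 at 1 kb and 0.042 at 5 kb. The uncalled Rxra turned to 0.075 under TBT and to -0.043 under rosiglitazone with ERCC scaling, and under rosiglitazone to -8.89e-04 without a filter and -8.41e-05 with 12 libraries. The uncalled Ezh2 turned to -0.039 under rosiglitazone with ERCC scaling. The cause was not tested. Of the other values, 1505 of named genes kept their direction and side of the threshold, and 30 of named genes lost their call. Of those that answer a comparison, 195 were rated the same. For counts of calls this meant only a count within 1.5-fold of the main one, whatever the directions. TBT against rosiglitazone with ERCC scaling was rated the same, although its calls went from 1908 higher and 1690 lower to 2426 and 172.

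With the replicate number as a replicate block, calls were 223 for rosiglitazone and 169 for TBT against AGN194204, 3882 for TBT, and 27 H3K4me3 regions, which took in 16 of the 21 regions named in the report, so 5 of those calls ended. camera then called smooth muscle genes under TBT at adjusted p = 0.039 (0.073 without it). Whether the numbers pair the samples was not settled. Same-numbered RNA libraries correlated at -0.09 to 0.25, with medians per number from 0.018 to 0.164. Libraries of different numbers correlated at -0.28 to 0.26, with a median of -0.0085. Of 24 libraries, 8 correlated best with their own number, so a weak pairing stays open. Same-numbered ChIP libraries correlated at 0.0025 to 0.08 for H3K4me3 and at -0.04 to 0.05 for H3K27me3.

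The 12 libraries of each pair of groups were split in 100 ways, and the ChIP libraries in 35. RNA splits used fits of the 12 libraries compared, not the main fit. Only the real split (1) gave as many calls for the 7 results that follow. A chance division of these libraries thus hardly accounts for those calls. Differences between cultures or sequencing runs could not be tested this way, since the labels do not say which libraries share them. The real values and the highest of the others were 3283 and 0 for TBT, 236 and 16 for rosiglitazone, 3046 and 0 for AGN194204, 3418 and 368 for TBT against rosiglitazone, 61 and 34 for TBT against AGN194204, 3242 and 448 for AGN194204 against rosiglitazone, and 21 and 2 for H3K4me3 regions. For H3K27me3 regions the real value and the highest other were 0, which made all 35 splits count as large, so they say nothing of chance. At this depth and spread 22% of 2-fold changes were recovered in simulated data for H3K27me3 regions and 96% for H3K4me3 regions.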

Other observations

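Both tests of the difference between TBT and AGN194204 were chosen after the results were seen, and the cell cycle test was planned.

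Some gene sets also differed between TBT and AGN194204. Of the 77 genes that rosiglitazone raised, 63 were higher under TBT than under AGN194204, with a median difference of 0.11 on the log2 scale, and edgeR called 14 of them. Of the 53 that it lowered, 45 were lower under TBT, with a median of -0.14, and 12 were called. PPAR targets were higher in 21 of 28, with 5 called (camera with an estimated correlation, adjusted p = 6.81e-04 over 25 sets), and inflammatory genes lower in 14 of 17, with 2 called (adjusted p = 0.0060). Matrix genes were higher in 26 of 32, with 8 called, which did not pass with an estimated correlation (adjusted p = 0.058, camera). LXR targets were lower in 11 of 13 (adjusted p = 0.0065 by camera, 0.18 with an estimated correlation), with a median of -0.07. ERCC scaling turned that median to 0.01, but it moved the median of all genes by 0.0769, so the turn says nothing of the list against other genes.

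One hypothesis is that TBT carries a PPARγ response beyond its RXR response. The sets raised and lowered by rosiglitazone both went the way this needs (camera with an estimated correlation, p = 1.45e-08 and 9.63e-04; adjusted p = 3.62e-07 and 0.0060 over 25 sets). The rosiglitazone genes were picked against DMSO, which takes no part in TBT against AGN194204. Doses differed, so a stronger effect of 50 nM TBT in general may also give this, which was not tested.

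Another hypothesis is that RAR targets respond more to AGN194204. The list was lower under TBT in 9 of 13, with 3 called (camera with an estimated correlation, p = 0.0163, adjusted p = 0.058 over 25 sets), so it may not hold after adjustment. ERCC scaling turned the median of -0.07 to 0.01 by the same shift of all genes.

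A further hypothesis is that fewer cells divided under both compounds. The mean over cell cycle genes lay below all DMSO and rosiglitazone libraries in 12 of 12 treated libraries, which this may explain. With ERCC scaling 2 of the genes fell under each compound, while the list median went from -0.20 to -0.11 under TBT and from -0.18 to -0.17 under AGN194204. Only under TBT was the fall clearly smaller on that scale, by about the 0.0896 that all genes moved. Cell numbers were not analysed here.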
